A study of Homo sapiens with 18 samples.

How the data were processed

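Total RNA of J82, RT112 and 5637 cells, treated with PBS or with palbociclib, was labelled with biotin and hybridised to Affymetrix human whole-transcript arrays, per the labels' protocols. The deposited values are log2 summarised intensities per probe set in 1 table of 18 arrays and 70523 rows. RMA and Affymetrix Expression Console are named in the submitters' processing notes, with no version, and the genome build is not given in the sources used here. The log2 values reach 19.93, above the 16 at which log2 of a 16-bit scan ends, so a step that stretches the scale is in the deposited values and log2 differences cannot be read as fold changes of signal. The table has no detection p-values, and no intensity filter was set. Samples were grouped by line and treatment from the labels, with 3 arrays in each of 6 groups. No 2 arrays held identical values.

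Of the rows, 67528 are transcript clusters, 1437 exon rows and 1558 control rows. The platform annotation gave 1 symbol to 23781 probe sets, several to 1543 and none here to 45199. Only transcript clusters with 1 symbol were used for genes, and where a symbol had several probe sets (479 symbols) the one with the highest mean over the arrays fitted was kept, leaving 22465 genes. No symbol changed when checked through its Entrez number. Several probe sets of a gene named in the lists disagreed for CD44, whose log2 differences in RT112 ran from -0.19 to 0.76 (-1.26 to -0.81 in J82). Those of IER3 differed in size in J82, from 0.51 to 1.09 over 6 probe sets. Lists of genes were fixed before the data were examined: 19 lists of pathways and 4 of markers of other cell types. Of 745 list entries 664 matched a symbol, and 4 older histone names led to 1 symbol, H2BC5, which counted once, leaving 661 list members; the others were not analysed here.

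The line means of 5637 did not follow those of the other lines on transcript cluster rows, apart from those at the start of the table, so the names of those rows were not used. The fits that the design set out for all 3 lines together, which were the average, the overlap and the contrasts with 5637, were not run by gene, and J82 and RT112 took their place. This choice was made when the row names were checked, before any fit. Probe sets were chosen by the mean over those 12 arrays.

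Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend) over 12 arrays, with 8 residual degrees of freedom. Contrasts were palbociclib minus control in each line, the difference of the 2 responses, their mean, and the difference of the controls. P-values were adjusted by Benjamini and Hochberg over the 22465 genes, with a threshold of 0.05. The 5637 rows were fitted alone on 6 arrays. Lists were tested with camera (preset correlation 0.01), with the p-values adjusted over 92 tests. Of 48 calls, 9 held with the correlation estimated from the data. fry tested whether the members of a list moved one way on balance.

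Genes named in the text follow a rule fixed before the data were examined. For each line these are the 10 highest and 10 lowest log2 differences past the threshold with all 3 treated arrays on one side of the 3 controls, for the shared changes the 10 highest and 10 lowest by the mean, for the difference between lines the 5 highest and 5 lowest, all genes of the CDK4/6-RB axis, and the leading 4 members of each list. For the shared changes and the difference, J82 and RT112 stand in for all lines. The rule gives 220 genes, of which 126 are named; the others were left out for length, a choice made with their values known, so counts over the named genes are not independent of the outcome. Small RNAs, uncharacterised loci, clone names and receptor segments were left out.

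Alternatives set beforehand were a replicate block, a shift of arrays to one median, a second quantile normalization, bright genes only, the mean of probe sets, all deposited probe sets, eBayes without a trend or with robust priors, array weights, a log2 difference of at least 1, each line alone, and each array left out. Tested on simulated data with 200 changed genes, the fit recovered 94% of changes of 1 and 100% of changes of 2 in J82, and 90% and 100% in RT112, over 22465 genes. For the 67528 rows of 5637 it recovered 79% and 99%. False calls numbered 14 in J82, 11 in RT112 and 13 in 5637. With a list shifted by -0.5 in simulated RT112 arrays camera called that list and 0 others. Genes were simulated as independent of each other, so this does not test calls that arise from correlated genes. Each gene had the same spread on all arrays, so the recovery does not cover an array that stands apart, such as RT112 palbociclib replicate 1.

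To test whether the 5637 rows stand in another order, each chromosome's rows were placed along the identifiers by level alone, with a left-to-right hidden Markov model. Several simpler alignments were tried first. The simulated reordering used for its check follows the same model. The placement serves only as a test of row order, and no gene or list value is taken from it. A planned test of RB1 status through the G1/S genes of 5637 was run on that order, and its value is left out because it rests on gene names inferred from row order.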

Results

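Human bladder cancer cells of 3 established lines, J82, RT112 and 5637, were profiled after exposure to palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, at its IC50, or to PBS as the control. Total RNA was read on 18 whole-transcript arrays, 3 for each of the 6 combinations of line and treatment, and the labels describe the 3 as separate dishes. The question was which transcripts changed under the drug within each line. Array medians lay between 4.8 and 5.21 on the log2 intensity scale. The lowest correlation between 2 arrays of a group was 0.973, in RT112 under palbociclib, where replicate 1 had a median of 5.21 against 4.83 and 4.8 in its 2 partners. The number of arrays limits the precision of the values, and differences are on the deposited log2 scale, written with their standard error (SE) from limma. That SE rests on 1 estimate of the spread per gene over the arrays of J82 and RT112 together. It does not measure the spread within 1 line.

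Row names held for J82 and RT112 but not for 5637. Across the 67528 transcript cluster rows, the line means of J82 and RT112 correlated with r = 0.94, whereas 5637 correlated with r = 0.027 with either. On the 1558 control rows 5637 correlated with J82 at r = 0.976 and on the 1437 exon rows at r = 0.944, and within its own groups no pair of 5637 arrays fell below r = 0.983. These are correlations across rows, which are not independent replicates. Gene-level comparisons therefore used the 12 arrays of J82 and RT112, and 5637 was compared with its own controls as rows without gene names.

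**Figure D1:**
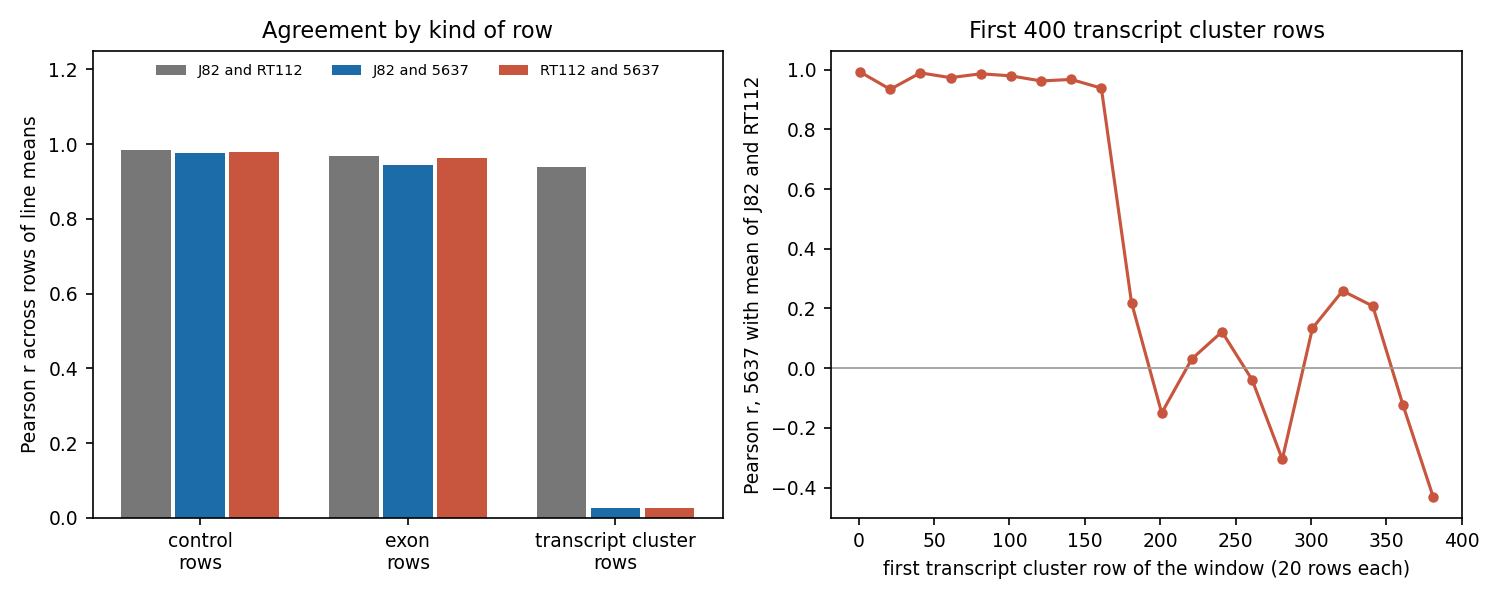
Pearson r across rows of the line means, by kind of row (left, bars from 0), and r of 5637 with the mean of the other lines in consecutive windows of 20 transcript cluster rows (right, first row of each window on the horizontal axis). Agreement of 5637 is 0.938 in the window that starts at row 161 and 0.22 in the window that starts at row 181.

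In J82 under palbociclib 24 of 43 genes of the lysosome and autophagy list rose, 14 of 31 of the integrated stress and unfolded protein response list rose and 2 fell, and 33 of 67 of the G2/M and mitosis list fell. These 3 lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.0708, adjusted p = 0.112 and adjusted p = 0.0832 with an estimated correlation). The strongest rises were TNFAIP6, a hyaluronan-binding secreted protein, by a log2 difference of 3.51 ± 0.29 (SE, n = 3 per group, adjusted p = 9.57e-06), and HSD17B14, a steroid dehydrogenase, by 3.30 ± 0.17 (adjusted p = 3.41e-07). They were followed by TNFAIP3, an inhibitor of NF-kB signalling (2.85), SAT1, a polyamine acetyltransferase (2.83), the endolysosomal channel gene MCOLN3 (2.76), KLHDC7B (2.71), the stress cytokine GDF15 (2.68), MYO16-AS1 (2.61), the serine synthesis enzyme PSAT1 (2.59) and the bradykinin receptor BDKRB2 (2.55). The largest fall was that of IGFBP5, a binding protein of insulin-like growth factors, at -3.23 ± 0.18 (adjusted p = 3.41e-07). MGARP (-2.95), the matrix protein THBS1 (-2.75), the endocytic receptor LRP2 (-2.68), the keratin KRT18 (-2.56), SLC12A3 (-2.52), the ephrin receptor EPHA2 (-2.45), GRPR (-2.36), the GDNF receptor GFRA1 (-2.35) and RUNX1-IT1 (-2.31) also fell. For TNFAIP6 the SD was 0.358 in J82 controls and 0.805 under palbociclib, against 0.068 and 0.094 in RT112. Its SE, shared by both lines, is therefore held down by the RT112 arrays. GDF15 started at 4.12 and GRPR ended at 4.05, below the median of every array, so the background limits the size of these 2 differences. In total 1213 of 22465 genes were higher and 624 lower at an adjusted p under 0.05, which is 8.18% of the genes. After the arrays were shifted to one median the split became 830 higher and 695 lower, and after quantile normalization 1226 and 1075. The higher genes numbered 662 without palbociclib replicate 3 (650 lower), 772 without control replicate 1 and 723 without control replicate 3, and the lower ones 400 without palbociclib replicate 2. The total of 1837 became 1147 without control replicate 3, 1045 with J82 fitted alone, 1054 genes with 1 symbol when all deposited probe sets were tested, and 535 with a log2 difference of at least 1 required as well (297 higher and 238 lower). It was 2416 without RT112 palbociclib replicate 1, an array of the other line that enters the same fit. In 5377 genes (23.9%) the palbociclib and control arrays of J82 did not overlap, where chance gives 10%.

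Of 67 measured members of the G2/M and mitosis list, 33 fell in J82 and none rose (46 fell when adjusted over the list alone), with a mean log2 difference of -0.68 in J82 and an SD over members of 0.52. The list passed camera with a preset correlation (adjusted p = 6.98e-33) and not with an estimated one (adjusted p = 0.0832 with an estimated correlation). The kinesin KIF20A fell by 2.18 ± 0.18, the cytokinesis protein ANLN by 2.01 ± 0.17 and the mitotic kinase PLK1 stood at -2.0 ± 0.23. Genes of G1/S and DNA replication did not fall as a group in J82. Of 55 measured members 5 rose and none fell (10 rose and 2 fell when adjusted over the list alone), the mean was 0.15, and the list did not pass camera (adjusted p = 0.194; 0.928 as adjusted p with an estimated correlation). It passed as higher without control replicate 1 (0.19), and the mean was 0.051 without palbociclib replicate 3. DTL, a substrate receptor of a replication-coupled ubiquitin ligase, rose by 0.87 ± 0.15, the chromatin assembly factor CHAF1B by 0.76 ± 0.15, the clamp loader subunit RFC3 by 0.88 ± 0.21 and the single-strand binding protein RPA2 by 0.77 ± 0.17. Without control replicate 3 the calls of RFC3 (0.79) and RPA2 (0.70) were lost, as they were after the arrays were shifted to one median (0.83 and 0.72), and that of RFC3 also without palbociclib replicate 3 (0.76). The list of replication-dependent histones had a mean of -0.13 over 21 members, of which 1, H2AC6, rose by 1.59 ± 0.37 and 1, H1-2, fell by 0.93 ± 0.24, the same numbers as when adjusted over the list alone. The call of H2AC6 was lost after the shift to one median (1.54) and without control 3 (1.48), and that of H1-2 without control 1 (-0.82), control 3 (-0.88) and palbociclib 2 (-0.765). The camera test was at the threshold (adjusted p = 0.0498; adjusted p = 0.652 with an estimated correlation), and the mean was 0.001 without palbociclib replicate 2, -0.017 without control replicate 1 and -0.16 without palbociclib replicate 3, where the list did not pass, as it did not without RT112 control replicate 2 (-0.13). It was -0.19 without control replicate 3 and -0.23 without palbociclib replicate 1.

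Of 43 measured members of the lysosome and autophagy list 24 rose in J82 and none fell (32 rose when adjusted over the list alone), with a mean of 0.73 and an SD over members of 0.59. The list passed camera with the preset correlation (adjusted p = 3.71e-17) but not otherwise (adjusted p = 0.0708 with an estimated correlation). RRAGD, a GTPase of the lysosomal nutrient-sensing complex, rose by 2.50 ± 0.18, the acid ceramidase gene ASAH1 by 2.47 ± 0.19, the hexosaminidase gene HEXA by 1.62 ± 0.19 and GPNMB by 1.37 ± 0.15. SQSTM1, an autophagy receptor, rose by 0.56 ± 0.12, a call lost without control replicate 2 (0.53) and after the shift to one median (0.51). Of 31 members of the integrated stress and unfolded protein response list 14 rose and 2 fell (16 and 2 when adjusted over the list alone), with a mean of 0.67. For this list camera gave an adjusted p of 1.47e-09 with the preset correlation (adjusted p = 0.112 with an estimated correlation). The transcription factor gene DDIT3 rose by 2.51 ± 0.24, the mitochondrial serine hydroxymethyltransferase SHMT2 by 1.71 ± 0.18, the asparagine synthetase ASNS by 1.33 ± 0.14 and the serine synthesis enzyme PHGDH by 0.93 ± 0.11. Among 32 senescence-associated secretory genes 4 rose and 5 fell (6 and 5 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.74). IL6 rose by 2.37 ± 0.35 and CXCL8 by 1.10 ± 0.16, whereas IGFBP5 fell.

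In RT112 under palbociclib 50 of 55 genes of G1/S and DNA replication, 15 of 21 histone genes and 66 of 67 genes of G2/M and mitosis fell, and 19 of 24 genes of cholesterol synthesis rose. With an estimated correlation camera passed the first 3 of these lists and not cholesterol synthesis (adjusted p = 0.0526 with an estimated correlation). The histone genes H2BC3 and H2BC14 fell, with log2 differences of -6.35 ± 0.27 (n = 3 per group, adjusted p = 7.83e-09) and -6.07 ± 0.23 (adjusted p = 2.88e-09), and DTL fell by 5.54 ± 0.15 (adjusted p = 1.4e-10). They were followed by the histone genes H2BC9 (-5.52), H2BC10 (-4.83), H2AC21 (-4.28) and H4C3 (-4.14), the thymidylate synthase TYMS (-4.53), the primase subunit PRIM1 (-4.25) and the replication licensing factor CDC6 (-4.25). Under palbociclib H2BC3 stood at 4.83 and H2BC14 at 3.51, near or below the array medians. The background limits the size of these falls, as it does for H2BC10 at 4.60. Upward, 3 enzymes of sterol synthesis led: MSMO1 at 4.0 ± 0.36 (adjusted p = 5.52e-06), SQLE at 3.82 ± 0.33 (adjusted p = 3.47e-06) and HMGCS1 at 3.62 ± 0.30 (adjusted p = 2.48e-06). DHCR7 (2.46), ERG28 (2.45) and ACAT2 (2.22), also of sterol metabolism, rose, as did the arrestin-like genes TXNIP (2.43) and ARRDC4 (2.16), TCP11L2 (2.30) and CYP1A1, a target of the aryl hydrocarbon receptor (2.21 from a control level of 4.48, where the background limits the size of the rise). In total 1112 of 22465 genes were higher and 793 lower, which is 8.48%. After the arrays were shifted to one median the split became 632 higher and 794 lower. The higher genes numbered 1818 without palbociclib replicate 1 (1147 lower). Higher and lower genes were 608 and 576 without control 1, 544 and 587 without control 2, 594 and 598 without control 3, 604 and 606 without palbociclib 2 and 568 and 629 without palbociclib 3. The total of 1905 became 2965 without palbociclib replicate 1, the array that stood apart, and between 1131 and 1210 without any other RT112 array (control 1 1184, control 2 1131, control 3 1192, palbociclib 2 1210, palbociclib 3 1197). It became 5780 with array weights, which gave that array a weight of 0.113, 1018 genes with 1 symbol when all deposited probe sets were tested, and 595 with a log2 difference of at least 1 required as well (221 higher and 374 lower). In 5114 genes (22.8%) the groups did not overlap, where chance gives 10%.

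Genes of the cell cycle fell in RT112. Of 55 measured G1/S and DNA replication genes 50 fell and none rose (53 fell when adjusted over the list alone), with a mean log2 difference of -2.04 and an SD over members of 1.16. Besides DTL and CDC6, the chromatin regulator ATAD2 fell by 3.79 ± 0.13 and the helicase HELLS fell by 3.28 ± 0.13. Of 67 G2/M and mitosis genes 66 fell and none rose (66 fell when adjusted over the list alone), with a mean of -2.09, among them CCNA2, which encodes cyclin A2 (-3.79 ± 0.19), the condensin subunit NCAPG (-3.76 ± 0.20), ANLN (-3.42 ± 0.17) and the centromere protein chaperone HJURP (-3.23 ± 0.16). Of 21 replication-dependent histone genes 15 fell and none rose (17 fell when adjusted over the list alone), with a mean of -2.40 and a range over members from -6.35 to 0.01. These 3 lists passed camera with the preset correlation (adjusted p = 2.43e-101, 2.99e-110 and 4.03e-30) and with an estimated one (adjusted p = 0.00631, 0.0121 and 0.0121 with an estimated correlation). Of 33 DNA repair genes outside replication 17 fell and none rose (19 fell and 2 rose when adjusted over the list alone), with a mean of -0.84, including the helicase BRIP1 at -3.25 ± 0.19 and the polymerase POLQ at -2.29 ± 0.13. This list passed camera with the preset correlation (adjusted p = 1.25e-19) and not with an estimated one (adjusted p = 0.0708 with an estimated correlation).

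Of 24 measured cholesterol synthesis genes 19 rose in RT112 and none fell (21 rose when adjusted over the list alone), with a mean of 1.57 and an SD over members of 1.09. Camera gave an adjusted p of 3.95e-26 with the preset correlation (adjusted p = 0.0526 with an estimated correlation). Besides MSMO1, SQLE and HMGCS1, the mevalonate pathway enzyme MVD rose by 1.93 ± 0.17. Of 43 lysosome and autophagy genes 13 rose and 1 fell (18 and 1 when adjusted over the list alone), with a mean of 0.45. The autophagy gene WIPI1 rose by 1.77 ± 0.19 and FNIP1, a folliculin partner, by 1.74 ± 0.21, SQSTM1 rose by 0.65 ± 0.12, and the galactosidase gene GLA fell by 0.99 ± 0.17 (list adjusted p = 8.5e-08; adjusted p = 0.224 with an estimated correlation). In the integrated stress and unfolded protein response list 6 of 31 rose and none fell (10 rose when adjusted over the list alone), with DDIT4 at 1.89 ± 0.15, HERPUD1 at 1.41 ± 0.20, CHAC1 at 0.63 ± 0.12 and the transcription factor ATF4 at 1.22 ± 0.20 (list adjusted p = 0.0017; adjusted p = 0.389 with an estimated correlation). Of 28 hypoxia and glycolysis genes 9 rose and none fell (14 rose when adjusted over the list alone), with NDRG1 at 1.72 ± 0.17, VEGFA at 1.68 ± 0.25 and ALDOC at 1.09 ± 0.10 (list adjusted p = 2.46e-06; adjusted p = 0.177 with an estimated correlation). Among 32 senescence-associated secretory genes 5 rose and 1 fell (5 and 2 when adjusted over the list alone), with the chemokine CCL20 at 1.68 ± 0.22 and IL1A at 1.0 ± 0.14, and the list did not pass camera (adjusted p = 0.801).

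**Figure D2:**
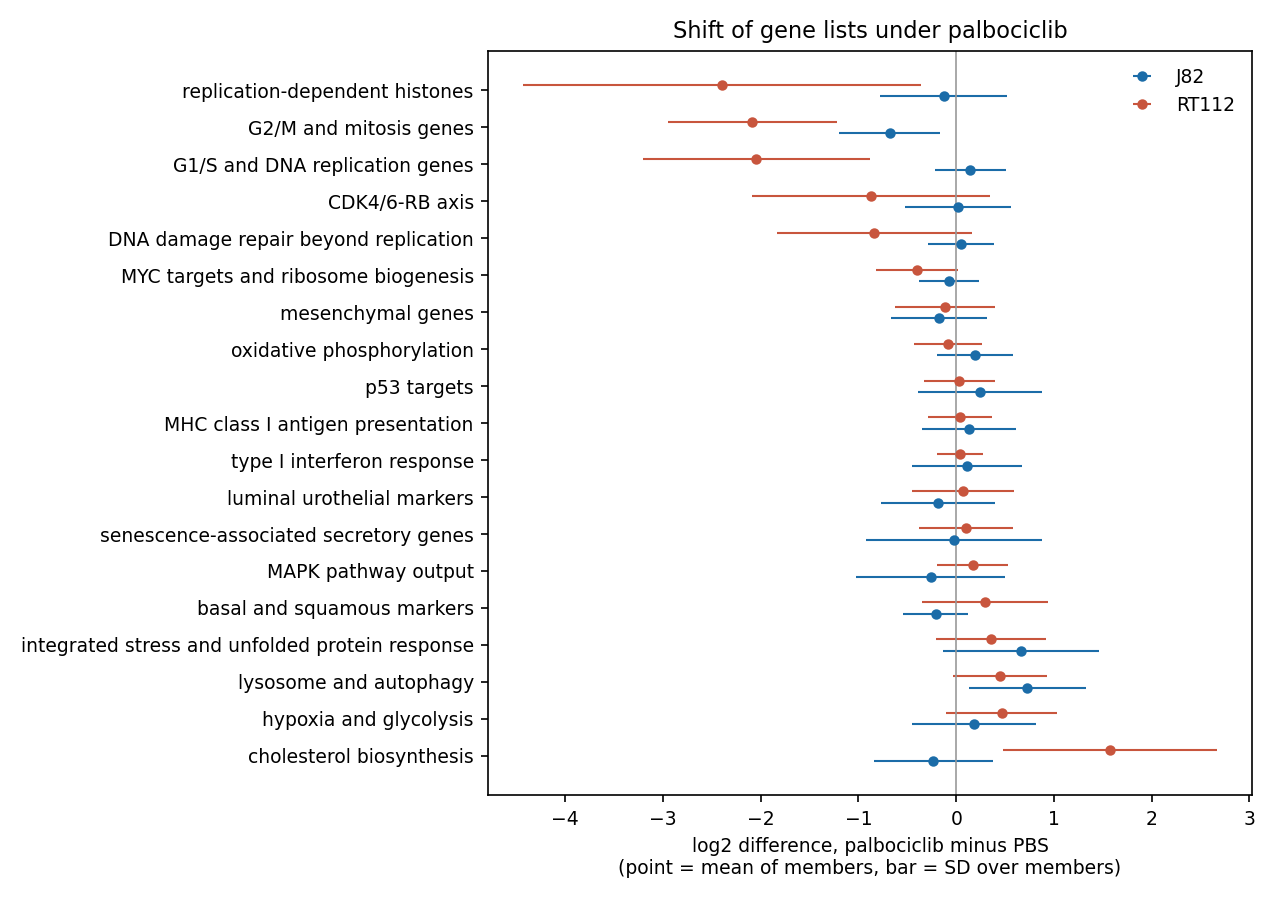
Mean log2 difference of the members of each gene list, palbociclib minus PBS, in J82 (blue) and RT112 (red), with bars of 1 SD over members. The G1/S list lies at 0.15 in J82 and -2.04 in RT112, and the cholesterol list at -0.24 and 1.57.

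Some genes changed in the same direction in both lines. Averaged over J82 and RT112, 2016 genes were higher and 1041 lower. After quantile normalization the split was 2000 and 1709, and after the shift to one median 1305 and 1217. The total of 3057 became 5075 with array weights, 1899 genes with 1 symbol when all deposited probe sets were tested, and 356 with a log2 difference of at least 1 required as well (140 higher and 216 lower). A call on the average does not require a change in each line. Of 55 G1/S genes 43 fell on average, though none fell in J82. Genes that passed in each line with one sign numbered 393, of which 282 were higher and 111 lower, where independent lists of these sizes would share 60 and 22. The lines shared no control arrays, but their tests shared 1 estimate of the spread per gene. Genes with a small spread pass more easily in both, so the numbers for independent lists may be too low. Opposite calls numbered 22 (higher in J82, lower in RT112; 42.8 for independent lists) and 23 (30.9 for independent lists). The count of 393 became 643 without RT112 palbociclib replicate 1, and 260, 234 and 247 without RT112 control replicates 1, 2 and 3. It was 252 after the shift to one median, 602 after quantile normalization, 838 with array weights, 170 genes with 1 symbol when all deposited probe sets were tested, and 75 with a log2 difference of at least 1 required as well. Across the 22465 genes, which are not independent replicates, the log2 differences of the lines correlated with Pearson r = 0.284 and Spearman rho = 0.266.

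Among the shared rises were TXNIP (2.50 ± 0.29 in J82, 2.43 ± 0.29 in RT112), SAT1, TNFAIP3, SLFN5 (2.47 and 1.66), the phosphatase DUSP10 (2.01 and 1.74), EPB41L4A-AS1 (1.97 and 1.55), TCP11L2 (1.10 and 2.30), DDIT3 (2.51 and 0.87) and the Rag GTPase genes RRAGD (2.50 and 0.95) and RRAGC (2.14 and 1.14). In RT112 the calls of SAT1, RRAGC and DDIT3 were lost without some single arrays. SAT1 stood at 1.68 and had 1.53 without control 1, 1.54 without palbociclib 2 and 1.48 without palbociclib 3, and RRAGC had 1.01, 0.97 and 1.06 without the same arrays. The call of DDIT3 in RT112 was lost after the shift to one median (0.83), after quantile normalization (0.81), without J82 control 2 (0.87) and without each RT112 array (control 1 0.92, control 2 0.89, control 3 0.79, palbociclib 2 0.71, palbociclib 3 0.81) other than palbociclib 1. Shared falls were those of the mitotic genes ANLN, KIF20A (-2.18 and -2.62), PLK1 (-2.0 and -2.54), ASPM (-1.80 and -3.05), KNL1 (-1.29 and -2.68) and NUSAP1 (-0.87 and -3.08), of the proliferation marker MKI67 (-1.40 and -3.71), of CCNA2 (-0.97 and -3.79), of the topoisomerase TOP2A (-1.13 and -3.31) and of KRT18 (-2.56 and -1.25). The call of NUSAP1 in J82 was lost without control 1 (-0.63) and without palbociclib 2 (-0.73).

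The response of RT112 differed from that of J82 in 1027 genes, of which 412 had a higher and 615 a lower log2 difference in RT112. The largest differences downward were DTL (-6.42 ± 0.22, adjusted p = 2.07e-09), H2BC3 (-6.32), H2BC14 (-6.10), TYMS (-5.25) and PRIM1 (-4.68). Upward they were HMGCS1 (5.45 ± 0.42, adjusted p = 5.83e-06), MSMO1 (4.81), SQLE (4.67), MGARP (3.04) and RPL36AP33 (2.85). H2BC3 stood at 4.99 ± 0.16 (SD, n = 3) in J82 controls, near the array medians, against 11.18 ± 0.64 in RT112 controls. H2BC14 stood at 3.59 ± 0.05 (SD, n = 3) in J82 controls, below the median of every array, against 9.58 ± 0.66 in RT112 controls. For these genes the starting level limits the difference between lines. The count of 1027 became 1625 after quantile normalization, with a split of 781 and 844, 2384 with array weights (1223 higher and 1161 lower) and 522 genes with 1 symbol when all deposited probe sets were tested. The genes with a higher log2 difference numbered 720 without RT112 palbociclib replicate 1 and 265 without RT112 control replicate 1. Without J82 palbociclib replicate 3 the split was 500 higher and 475 lower. The total lay between 688 and 1517 without single arrays. Palbociclib was used at its IC50, and the concentration and time of exposure in each line are not given here. A difference in exposure therefore cannot be told apart from a difference between the lines.

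By list, the difference between the lines passed camera for the G1/S list with a mean of -2.19 (adjusted p = 4.56e-91; adjusted p = 0.00631 with an estimated correlation) and for the histones with -2.27 (adjusted p = 1.07e-21; adjusted p = 0.0252 with an estimated correlation). For G2/M genes it was -1.41 (adjusted p = 2.42e-50; adjusted p = 0.0522 with an estimated correlation), and for cholesterol synthesis 1.81 (adjusted p = 5.27e-27; adjusted p = 0.0522 with an estimated correlation). In J82, 4 of 24 cholesterol genes fell and none rose (5 fell and 1 rose when adjusted over the list alone), with HMGCS1 at -1.83 ± 0.30, NSDHL at -1.05 ± 0.18, IDI1 at -0.85 ± 0.18 and INSIG1, a regulator of sterol sensing, at -1.18 ± 0.33. The call of INSIG1 in J82 was lost after the shift to one median (-1.22), without J82 control 2 (-0.96), J82 control 3 (-0.90), J82 palbociclib 1 (-1.095) and J82 palbociclib 2 (-1.07), and without any of the RT112 arrays (-1.18). The mean of that list in J82 was -0.24 (adjusted p = 0.0174; adjusted p = 0.713 with an estimated correlation) and was -0.14 without control replicate 2 and -0.14 without control replicate 3, where it no longer passed, and -0.43 without control replicate 1. Basal and squamous markers differed by 0.50 (adjusted p = 1.08e-05; adjusted p = 0.0317 with an estimated correlation), with a higher log2 difference in RT112 in 7 of 27 and a lower one in none (9 and none when adjusted over the list alone), such as KRT13 (1.51) and TRIM29 (1.70). Within RT112 9 of 27 rose (10 when adjusted over the list alone), with KRT13 at 1.38 ± 0.20 and TRIM29 at 1.47 ± 0.23 (list mean 0.30, adjusted p = 0.0423; adjusted p = 0.23 with an estimated correlation). The RT112 list did not pass without J82 palbociclib 3 (0.30) or without RT112 control 1 (0.28), control 2 (0.27), palbociclib 2 (0.26) or palbociclib 3 (0.28). Within J82 2 of 27 fell (2 when adjusted over the list alone; list mean -0.21, adjusted p = 0.00186; adjusted p = 0.0822 with an estimated correlation).

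**Figure D3:**
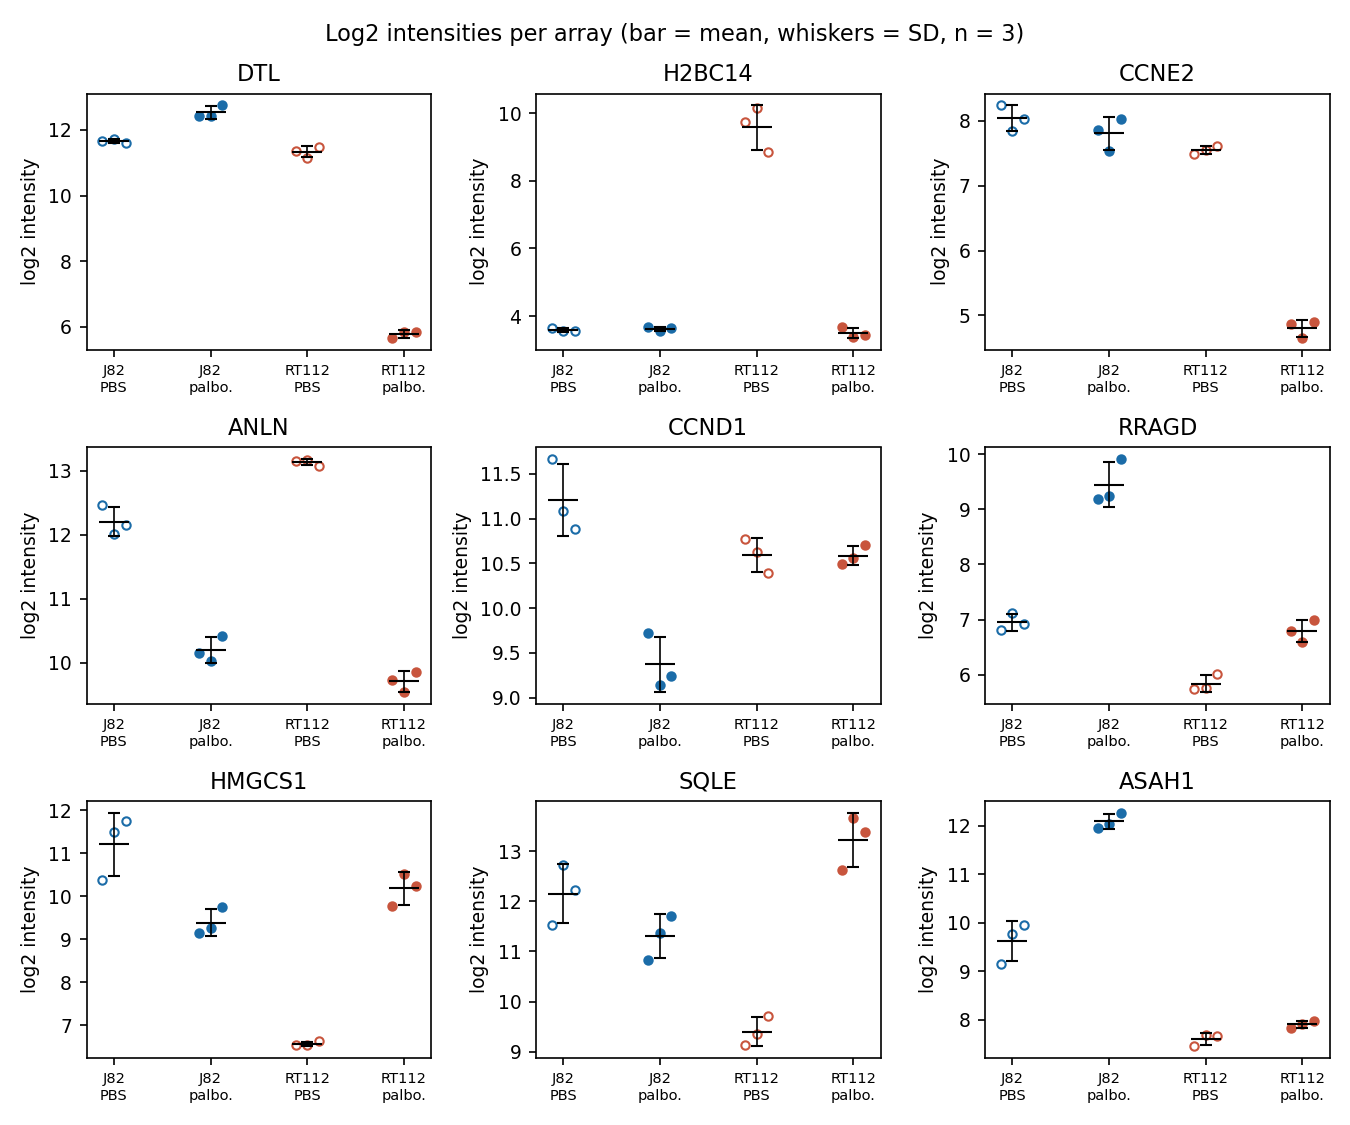
Log2 intensity of 9 genes on each array of J82 (blue) and RT112 (red) under PBS (open) and palbociclib (filled), with the mean and SD of 3 arrays. DTL stands at 11.33 in RT112 controls and 5.79 under palbociclib, and at 11.66 and 12.53 in J82.

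Within the CDK4/6-RB axis list, 12 of 25 measured genes fell and 1 rose in RT112, and 1 fell and 4 rose in J82, the same numbers as when adjusted over the list alone. As a list the axis passed camera in RT112 (mean -0.87, adjusted p = 6.76e-13; adjusted p = 0.0623 with an estimated correlation), not in J82 (mean 0.02, adjusted p = 0.779), and its difference between lines was -0.89 (adjusted p = 1.53e-10; adjusted p = 0.0819 with an estimated correlation). In RT112 the transcription factor genes E2F8 (-3.31 ± 0.17), E2F7 (-2.88), E2F1 (-1.53) and E2F2 (-0.75), the pocket protein gene RBL1 (-3.26), CCNE2 (-2.75) and CCNE1 (-0.67), both encoding E-type cyclins, CDK2 (-2.31), CDC25A (-1.60), SKP2 (-1.58), CDK4 (-1.41) and RB1 (-0.74) fell, and RBL2 (0.95 ± 0.20) rose. CCNE2 ended at 4.8, so the background limits the size of its fall. In J82 CCND1, which encodes cyclin D1, fell by 1.84 ± 0.21 (adjusted p = 0.000141), and the CDK inhibitor genes CDKN2B (1.01 ± 0.19) and CDKN1B (0.70 ± 0.15), CDK4 (0.93 ± 0.23) and E2F2 (0.47 ± 0.11) rose. CCND1 stood at -0.01 ± 0.21 in RT112, and the difference between lines was 1.83 ± 0.30 (adjusted p = 0.00256). Without 1 array the calls of CDK4 in J82 (0.88, 0.82, 0.80 and 0.87 without control 2, control 3, palbociclib 1 and palbociclib 3) and of E2F2 in J82 (0.44, 0.47, 0.44 and 0.44 without the same arrays) were lost, as was that of CCNE1 in RT112 (-0.65, -0.62, -0.68 and -0.60 without control 1, control 2, palbociclib 2 and palbociclib 3). CDK6, CCND2, CCND3, E2F3, CDKN1A, CDKN1C, CDKN2A, CDKN2D and FBXW7 passed in neither line, with log2 differences from -0.23 to 0.13 in J82 and from -0.32 to 0.25 in RT112.

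Before treatment the lines already differed in 17 of these 25 genes (13 to 17 with 1 array left out). The share over all genes is not given here, so this count does not set the list apart. In J82 controls SKP2 (12.98 ± 0.12, SD, n = 3, against 10.82 ± 0.14 in RT112 controls), CDKN2B (7.07 against 5.12), CDKN2A (7.42 against 5.63), CCNE1 (8.91 against 7.19), RB1 (10.34 against 8.78) and CDKN1B (7.26 against 6.10) were higher. CDK6 (6.83 against 8.66) and E2F8 (7.92 against 9.26) were lower. CDK4 stood at 13.99 ± 0.29 and 13.48 ± 0.20, a difference that did not pass (adjusted p = 0.135). Whether arrays of the lines were normalized in one run is not given in the sources used here, which bears on these levels. Its effect on the changes within a line was not tested.

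In 5637, 1441 of 67528 transcript cluster rows were higher under palbociclib and 1040 lower, in a fit of its 6 arrays alone. The differences past the threshold ran from -5.27 to 5.68, and 664 rows were higher and 481 lower by at least 1. Fitted in the same way, J82 had 453 rows higher and 418 lower (337 and 329 by at least 1), and RT112 588 and 662 (359 and 544 by at least 1). The SD of all log2 differences was 0.344 in 5637, 0.35 in J82 and 0.347 in RT112, with a median SE of 0.142, 0.149 and 0.173. The higher counts therefore do not show a larger response in 5637. The 5637 split became 772 and 533 after the shift to one median, and 1374 and 1524 after quantile normalization. The total of 2481 became 893 without control replicate 3, and 888, 632 and 759 without palbociclib replicates 1, 2 and 3. It was 6430 with array weights and 1305 after the shift to one median. No gene is named for these rows, and the 5637 response was not compared with that of the other lines gene by gene.

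Markers of other cell types were measured as well. The lists of 10 endothelial and 8 smooth muscle markers had means between -0.04 and -0.01 in both lines and did not pass camera (adjusted p from 0.412 to 0.641). These means turned direction with single arrays left out, from -0.06 to 0.005 (endothelial) and from -0.06 to 0.03 (smooth muscle) in J82, and from -0.14 to 0.06 and from -0.15 to 0.03 in RT112. Without RT112 palbociclib replicate 1 the endothelial (-0.14) and immune (-0.22) lists passed as lower in RT112, and the fibroblast mean was -0.01. Of 16 immune markers 1 passed, LAPTM5, which fell by 1.64 ± 0.13 in RT112. Of 10 fibroblast markers 3 fell in J82, among them POSTN at -1.71 ± 0.16 from a control level of 8.01 and PDGFRB at -1.0 ± 0.16 from 7.21, and the list mean in RT112 was 0.08 (adjusted p = 0.82). The fibroblast list had a mean of -0.35 in J82 (adjusted p = 0.00186; adjusted p = 0.319 with an estimated correlation).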

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

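Responses that differed between RT112 and J82, by the interaction term of the limma fit, are listed here as RT112 minus J82. The test of row order, the scaling test and the test of single arrays were set before their results were seen; those of a floor, of a response in J82 (in place of a count of splits), of array noise, of a shared lysosomal response and of starting levels of sterol genes were chosen after. The difference passed the threshold in 1027 genes. Of 100 splits of the arrays within lines, drawn from 200, 1 gave as many, the real one, and the highest of the others gave 510. Exchanging control and palbociclib in J82 alone is a split outside those 100. It turns the difference into the sum of the responses, which gives the 3057 calls of the average. The splits test for no drug response in either line, so they do not decide whether chance made the responses differ. The concentration used in each line is not given here, so a role of dose in any of these differences was not tested.

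The first pattern is the larger fall of cell cycle genes in RT112, with differences of list means of -2.19 for G1/S, -1.41 for G2/M (adjusted p = 0.0522 with an estimated correlation), -2.27 for histones, -0.89 for the CDK4/6-RB axis (adjusted p = 0.0819 with an estimated correlation) and -0.89 for DNA repair (adjusted p = 0.0923 with an estimated correlation). The tables argue against a floor in J82, since the median G1/S gene of the J82 controls lay 1.73 above its level in RT112 under palbociclib, with 54 of 55 genes above. That test replaced one of control levels (median 0.086 higher in RT112), which decided nothing, and does not cover histones such as H2BC3 and H2BC14, at 4.99 and 3.59 in J82 controls. They argue against array scaling, since the G1/S difference was -2.18 after quantile normalization, and against a lack of any response in J82, where the G2/M list had a mean of -0.68 and passed fry (adjusted p = 0.00307), though not camera with an estimated correlation (adjusted p = 0.0832). A candidate explanation from background knowledge is that RT112 is known as an RB1-proficient line and J82 as RB1-deficient, but a single line of each kind was compared by gene, RB1 mRNA was higher in J82 controls (10.34 against 8.78), which does not measure the protein, and the value of a test through 5637 is left out, so this stays open beside every other difference between the lines.

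The next pattern is the rise of cholesterol synthesis genes in RT112, whose list differed by 1.81 (adjusted p = 0.0522 with an estimated correlation, and adjusted p = 0.0526 within RT112). A single array is argued against, since the RT112 mean was at least 1.51 with any RT112 array left out. A lysosomal response that raises sterol genes as well would raise them in J82 too. There 24 of 43 lysosome genes rose (32 when adjusted over the list alone, camera adjusted p = 0.0708 with an estimated correlation). The cholesterol mean in J82 was -0.24 (camera adjusted p = 0.713 with an estimated correlation). Sterol genes started higher in J82, which could hide a rise there, so this explanation stays open for RT112. That test replaced one of the lysosome difference (-0.28). A higher starting level in J82 may contribute, since the median gene stood at -1.04 in RT112 relative to J82 controls (16 of 24 lower, 2 higher), and at 0.43 under palbociclib. No spread over members is given for that median, so a role of the starting level stays open.

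Other lists that differed were lysosome and autophagy (-0.28), luminal markers (0.27), basal and squamous markers (0.50), integrated stress (-0.31), MAPK output (0.43), MYC targets (-0.33), hypoxia and glycolysis (0.28), oxidative phosphorylation (-0.28) and fibroblast markers (0.43). Apart from basal and squamous markers (adjusted p = 0.0317 with an estimated correlation), these calls were lost with an estimated correlation, with an adjusted p from 0.2 to 0.652. Without RT112 palbociclib replicate 1 lysosome (-0.23), integrated stress (-0.205), MYC targets (-0.24) and oxidative phosphorylation (-0.27) did not pass, nor did integrated stress without J82 control 1 (-0.24) and RT112 control 3 (-0.26), and oxidative phosphorylation without J82 control 3 (-0.19). Without J82 palbociclib 3 lysosome was -0.19 and integrated stress -0.20.

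The values that follow are signed differences between the lines and do not say which line changed more. Of the genes named in the text, 54 had a lower log2 difference in RT112 than in J82: TNFAIP6 -3.20, HSD17B14 -3.03, MCOLN3 -2.60, KLHDC7B -2.69, GDF15 -2.54, MYO16-AS1 -2.86, BDKRB2 -2.80, H2BC3 -6.32, H2BC14 -6.10, DTL -6.42, H2BC9 -4.56, H2BC10 -4.13, TYMS -5.25, H2AC21 -3.90, PRIM1 -4.68, CDC6 -4.44, H4C3 -3.79, RRAGD -1.55, DDIT3 -1.64, ANLN -1.41, MKI67 -2.30, CCNA2 -2.81, TOP2A -2.19, KNL1 -1.39, NUSAP1 -2.22, CDK4 -2.34, CDK2 -2.19, CCNE2 -2.51, RB1 -1.03, RBL1 -3.41, E2F1 -1.54, E2F2 -1.22, E2F7 -2.79, E2F8 -3.16, CDC25A -1.36, CHAF1B -3.10, ATAD2 -3.47, HELLS -2.88, HJURP -3.49, NCAPG -3.18, ASAH1 -2.17, HEXA -1.60, GPNMB -1.19, GLA -1.07, SHMT2 -1.51, ASNS -0.86, PHGDH -1.07, IL6 -2.37, ADM -1.50, POLQ -2.19, BRIP1 -3.23, LAPTM5 -1.66, RPA2 -0.98, RFC3 -2.90. A higher log2 difference in RT112, which includes genes that fell in J82 alone, was found for 34: IGFBP5 2.82, MGARP 3.04, THBS1 1.84, LRP2 2.71, KRT18 1.30, SLC12A3 2.42, EPHA2 2.82, GRPR 2.34, GFRA1 2.23, RUNX1-IT1 1.94, MSMO1 4.81, SQLE 4.67, HMGCS1 5.45, DHCR7 2.21, ERG28 2.42, ACAT2 1.89, CYP1A1 2.10, ARRDC4 2.65, RPL36AP33 2.85, CCND1 1.83, FNIP1 1.18, DDIT4 1.21, IL1A 0.93, NSDHL 2.51, IDI1 2.2, MVD 1.97, NDRG1 1.41, ALDOC 1.13, KRT13 1.51, TRIM29 1.70, POSTN 1.91, PDGFRB 0.94, IFIT1 1.39, INSIG1 2.70. LRP2, GRPR, POSTN and IFIT1 stood at 4.66, 3.76, 4.43 and 4.47 in RT112 controls, and LAPTM5 at 5.00 in J82 controls, near or below the array medians, so the background limits a fall in that line, as for H2BC3 and H2BC14 in J82.

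The count of genes changed in J82 had 10 possible splits of its arrays, and in RT112 and 5637 likewise, too few for a share under 0.05. The real split gave 1837, 1905 and 2481 calls and the highest of the others 1, 0 and 1. For the average over J82 and RT112, 1 of 100 splits reached 3057, the real one, with at most 585 in the others. The exchange within J82 alone, outside these 100, gives the 1027 calls of the difference, also fewer. For the average this argues against chance with no drug response in either line. For the 393 genes changed in one direction in both lines 1 of 100 splits gave as many and the others at most 0, which follows from the few calls of other splits within a line and adds nothing to them.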

How the results depend on the processing

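The fit of 12 arrays, the averages and overlaps of 2 lines and the fit of the 5637 rows alone were chosen after the data were seen. The other settings were not, and the fit of all 18 arrays was the one planned. The planned average, overlap and contrasts with 5637 by gene were not run, because its row names did not hold. Of 5498 recomputed values of single genes, 84 lost and 39 gained a call. Of the values of lists, 83 lost and 18 gained a call. With a call before or after, 0 values of genes and 2 of lists turned direction; turns among values called in neither were not counted. The causes were not tested. Without detection calls, the level above background that limits each gene is unknown.

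Without single arrays the totals ranged from 1147 to 2416 in J82, from 1131 to 2965 in RT112, from 632 to 2249 rows in 5637, from 234 to 643 in both lines, from 2220 to 4150 for the average and from 688 to 1517 for the difference. Apart from 5637, the highest totals all arose without RT112 palbociclib replicate 1. With all deposited probe sets tested, called genes with 1 symbol numbered 1054 (J82), 1018 (RT112), 522 (difference), 1899 (average) and 170 (both), and called probe sets of any kind 1263 higher and 1015 lower in J82 and 983 and 848 in RT112. A log2 difference of at least 1 gave 535, 595, 356 (average), 75 (both) and 1145 (5637). Array weights gave 5780 in RT112, 2384 for the difference, 5075 for the average, 838 for both and 6430 in 5637. Quantile normalization gave 1625 for the difference and 602 for both, a shift to one median 252 for both and 1305 in 5637, and J82 alone 1045. The planned fit of all 18 arrays, with the 5637 rows as deposited, gave 1986 in J82 and 1981 in RT112.

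Same-numbered arrays shared only a number. Their deviations correlated at 0.172, 0.188 and 0.075 in J82, each best with its own number, at 0.086, -0.193 and 0.173 in RT112 and at -0.064, -0.293 and 0.011 in 5637. With the replicate block the counts were 1900 in J82, 1867 in RT112, 1095 for the difference, 3152 for the average, 417 for both and 1076 rows in 5637.

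List means keep their value under camera with an estimated correlation and under fry, which test them otherwise. Of 48 camera calls 9 held with an estimated correlation. Those lost included G2/M in J82 (-0.68) and between lines (-1.41), cholesterol in J82 (-0.24), RT112 (1.57) and between lines (1.81), and lysosome in J82 (0.73), RT112 (0.45) and between lines (-0.28). Among the lists that passed camera and are named in the text, fry did not pass histones (adjusted p = 0.65), cholesterol (0.559), luminal (0.0564), mesenchymal (0.0842) and MAPK output (0.0501) in J82, nor lysosome (0.134), luminal (0.0564), integrated stress (0.2), MYC targets (0.16), oxidative phosphorylation (0.234) and fibroblast markers (0.0564) between lines. The cholesterol mean in J82 also failed after the shift to one median (-0.28) and ran from -0.43 to -0.14 without single arrays. The lysosome difference failed with array weights (-0.18) and without RT112 palbociclib 1 (-0.23), over a range of -0.34 to -0.19. G1/S in J82 passed without control 1 (0.19), over a range of 0.051 to 0.202. The histone mean in J82 ran from -0.23 to 0.001 and the interferon mean from -0.12 to 0.26 without single arrays.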

Other observations

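Interferon response genes went both ways in J82 and the list did not pass camera (39 members, 4 rose and 2 fell, 5 and 2 when adjusted over the list alone, mean 0.11, adjusted p = 0.898). IFIT1 fell by 1.39 ± 0.25, IFI35 rose by 1.26 ± 0.26 and IFI44L rose by 1.14 ± 0.25, a call lost without J82 palbociclib replicate 3 (0.97). In RT112 the list mean was 0.04 (adjusted p = 0.754). Without J82 control replicate 1 the mean was -0.12 and the list passed as lower. Of 25 targets of p53, 3 rose and 1 fell in J82 and 21 did not pass (mean 0.24, median 0.13, 5 rose and 2 fell when adjusted over the list alone, list adjusted p = 0.0464; adjusted p = 0.537 with an estimated correlation). The list call in J82 was lost without J82 control 1 (0.23), J82 palbociclib 3 (0.18), RT112 palbociclib 1 (0.24) and RT112 palbociclib 3 (0.24). GDF15 had the highest value, and the list mean was 0.03 in RT112 (adjusted p = 0.945). ADM, a vasodilator peptide of the hypoxia list, rose by 1.93 ± 0.19 in J82, where 5 of 28 members rose and 1 fell (5 and 2 when adjusted over the list alone; list adjusted p = 0.603). MYC target and ribosome biogenesis genes fell in RT112 in 7 of 33 cases (11 when adjusted over the list alone; mean -0.40, adjusted p = 1.54e-09; adjusted p = 0.243 with an estimated correlation), and oxidative phosphorylation genes passed in neither line as a list (adjusted p = 0.14 in J82, 0.0659 in RT112). They passed in J82 without control 1 (0.24) and palbociclib 2 (0.27), and in RT112 without control 2 (-0.10), control 3 (-0.12), palbociclib 2 (-0.07) and palbociclib 3 (-0.11). Of 20 antigen presentation genes 2 rose and 1 fell in J82 and none passed in RT112, the same numbers as when adjusted over the list alone, and the list did not pass in J82 (adjusted p = 0.688) or RT112 (adjusted p = 0.723). Of 27 mesenchymal genes 8 fell in J82 (8 fell and 2 rose when adjusted over the list alone), with means of -0.18 in J82 (adjusted p = 0.00694; adjusted p = 0.373 with an estimated correlation) and -0.12 in RT112 (adjusted p = 0.127). Of 27 luminal markers 1 rose and 4 fell in J82, as when adjusted over the list alone, with KRT18 lowest (mean -0.19, median -0.06, list adjusted p = 0.0121; adjusted p = 0.267 with an estimated correlation). Of 21 MAPK output genes 2 rose and 4 fell in J82 (3 and 5 when adjusted over the list alone; mean -0.26, median -0.10, list adjusted p = 0.0127; adjusted p = 0.319 with an estimated correlation). Neither list passed in RT112 (adjusted p = 0.652 and 0.278).

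A hypothesis for the 5637 columns is that their transcript cluster rows stand in another order under unchanged identifiers. The test of noisy arrays was chosen after the result was seen, in place of a comparison with the lowest r of the other lines (0.973), which rested on RT112 palbociclib replicate 1. Noise that takes transcript cluster rows to r = 0.027 with the other lines would also part the arrays of a group or the other kinds of row, whereas the lowest r within a 5637 group was 0.983 and 5637 kept at least 0.944 with the other lines on control and exon rows. When 57698 of 65609 rows (87.9%) were placed by level with a posterior of at least 0.99, the palbociclib responses, which were not used to place them, correlated across 18636 probe sets with those of RT112 at r = 0.112 and of J82 at r = 0.054, against -0.007 and -0.019 as deposited. The highest of 100 decoy placements, shifted by 1 to 50 rows, gave 0.023 and 0.019. Over the same probe sets the J82 and RT112 responses correlated at r = 0.29, above both placed values. The decoys do not keep the match by level, so array effects that depend on level are not covered by them. The values go with a changed row order without settling it. In a simulated reordering of RT112 rows built on the same model 82.5% of rows were placed, and 99.78% of the placed rows were right. The order was inferred, not given, so no gene or list value of 5637 is drawn from it.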
